A study of Mus musculus with 28 samples.

How the data were processed

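Kidneys of mice carrying 1 of 3 forms of aquaporin-3 (Aqp3) were profiled by sequencing of polyadenylated RNA. Per the labels, the forms were wild type (WT), a mimetic of lysine acetylation (Q) and a mimetic of the deacetylated lysine (R), in males and in females. The mice had received no treatment, and the kidneys had been taken between 2 and 5 h of zeitgeber time, freed of the capsule and frozen. RNA had been isolated with a Zymo Direct-zol kit and sequenced on an Illumina instrument. The labels number the replicates of each group but give no litter, day or batch, and do not state that each library came from a separate animal. The p-values therefore measure the spread between libraries as the labels give them, which may in part be technical.

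The values used were the raw counts per gene deposited by the authors, as whole fragments over exons, with no scaling applied. Per the file headers, they had been made with featureCounts from Subread 2.0.1 on the Ensembl release 107 annotation of GRCm39, counting fragments, with no strand option given. No option for reads that map to several places was given, so such reads were left out by that tool's default. The submitters' processing notes list Trim Galore 0.6.7, SAMtools 1.6 and DESeq2 1.38.3 in addition, and the aligner was not given in the sources used here. The table held 56748 genes, of which 52073 had a symbol in the reference, and genes without a symbol held 0.669% of all counts. Every column of the table belonged to a labelled sample. Chromosomal neighbours, X-linked genes and transcript lengths were taken from GENCODE mouse release 21 on GRCm38, an older build than that of the counts, so genes were matched by identifier and no coordinates are given.

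Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 6 groups, which left 17573 genes holding 99.91% of all counts, 400 of them without a symbol. Libraries were scaled by TMM. One model with a mean for each of the 6 groups was fitted to all 28 libraries with 22 residual degrees of freedom, and the square root of the common dispersion was 0.176. The robust quasi-likelihood test was applied to 12 contrasts, of which 9 compared genotypes, 2 were interactions of sex and genotype and 1 compared the sexes in WT. Both-sexes contrasts are the mean of the male and the female contrast. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Levels are TMM-scaled counts relative to the library total (edgeR's cpm, written CPM) as mean ± SD over libraries. Log2 fold changes are the values fitted by edgeR with its default prior count. Their standard errors (SE) were derived from the test, as the absolute log2 fold change divided by the square root of the F statistic. Intervals of log2 fold changes rest on these SE, which are approximate, above all for large changes or low counts. A prior count of 2 was used for log2 CPM only. Confidence intervals are at 95%, a count of 0 was set against a floor of 3 counts over the group, and both cover counting error only where they are computed from counts.

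Before the data were examined, 32 gene lists with 418 genes were fixed for cell types of the kidney, for other cell types the tissue could hold, and for pathways that fit aquaporin-3 and the tissue. Of their genes, 2 were missing from the table, and 31 lists had at least 3 tested genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, two-sided, adjusted over the 31 lists of a contrast. They were tested again with the correlation estimated for each list, and with fry, which asks whether a list's genes move on balance in one direction. A member count "adjusted over the list alone" corrects the edgeR p over that list's genes only. Tested genes within 5 Mb of Aqp3 were set against all other genes in their share of changed genes with Fisher's exact test, one-sided. The same test on genes with an unadjusted p under 0.05 was not part of the plan.

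The named genes follow a rule fixed at the same time. All tested aquaporins are named in the genotype contrasts. Of a genotype contrast with 25 or fewer changed genes all changed genes are named, otherwise the 12 largest rises and 12 largest falls. Of the sex contrast the 8 largest in each direction are named, with a mean of at least 1 CPM and a direction kept after leaving out each library. Of each list described, up to 4 members with the smallest p are named whether or not they pass. Genes known only by a Gm or Rik name, unnamed genes, pseudogenes, Y-linked genes and Xist are counted but not named, unless a contrast has 5 or fewer changed genes. Genes named outside the rule are marked as chosen after their values were seen.

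The alternatives fixed in advance were DESeq2 size factors in the edgeR test, the Wald test of DESeq2 1.42.0, no filter on low counts, a replicate block, the library code of the descriptions as a covariate, a clock gene score as a covariate, only the libraries of the contrast, and leaving out each library in turn. Chosen after seeing the data were limma with voom and quality weights per library, and leaving out together the 2 libraries that stood apart (male Q replicate 4 and female Q replicate 5).

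The test was tried on simulated counts with the means, depths and dispersions of these libraries, in which 200 of 17573 genes had been changed by 1.5-, 2- or 4-fold. With 5 against 5 libraries as in male Q against WT it recovered 56.7%, 80.6% and 100% of them, and 4.24% of its calls were false. With 3 against 5 as in female R against WT it recovered 29.9%, 71.6% and 98.5%, and 5% of its calls were false. A list of 12 genes raised 1.5-fold was called by camera in each of the 5 simulated contrasts, and no other list was. The simulated genes were drawn independently of each other, so this does not show how often camera calls a list falsely where genes vary together. The changed genes had a mean of at least 1 CPM, all 200 were changed at once, and each gene had the same dispersion in every library. Genes of lower level, a contrast with few changed genes and libraries that stand apart were not simulated, so recovery there may be lower.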

Results

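The data are counts of polyadenylated RNA from 28 mouse kidney libraries in 6 groups of sex and Aqp3 genotype. There were 5 libraries in each of the male WT, male Q, male R, female WT and female Q groups and 3 in the female R group. Total counts per library ran from 14825417 to 21403804. They were 16332363 to 21403804 in male WT, 16360833 to 19951957 in male Q and 17608533 to 21283031 in male R. Totals in females were 14825417 to 19916030 in WT, 16159881 to 20178003 in Q and 15385005 to 20451510 in R. The first principal component of log2 CPM held 35.4% of the variance and parted male from female libraries, and the second held 11.4%. On the second, male Q replicate 4 lay at -82.0 and female Q replicate 5 at -43.3, the farthest from 0 of the 28 libraries. Mitochondrially encoded genes held 7.74% of the counts of male Q replicate 4 and 3.94% of those of female Q replicate 5, against 9.56 to 12.1% in the other 26 libraries. In the female WT group, replicate 2 had 0.515 CPM of Xist, the RNA that silences one X chromosome, against 214 to 435 CPM in the other 12 female libraries. Its 4 tested Y-linked genes summed to 0.468 CPM, against 121 to 164 CPM in male libraries.

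Aqp3, the glycerol and water channel of the basolateral membrane of collecting duct principal cells, is the edited gene, and its transcript level was compared between genotypes. It was read at 121 ± 17 CPM in male WT, 111 ± 7.78 in male Q and 113 ± 8.3 in male R (SD, n = 5 each). Female kidneys had 118 ± 15.7 CPM in WT and 111 ± 11.1 in Q (n = 5 each) and 124 ± 7.78 in R (n = 3). Each library held at least 1484 Aqp3 counts. The log2 fold change of Q against WT was -0.12 in males (95% interval -0.33 to 0.09) and -0.09 in females (-0.29 to 0.12). That of R against WT was -0.09 in males (-0.30 to 0.11) and 0.08 in females (-0.16 to 0.31). Over both sexes it was -0.10 for Q against WT (SE 0.0712), -0.01 for R against WT (SE 0.0768) and -0.10 for Q against R (SE 0.0767). Leaving out single libraries moved the estimate of Q against WT between -0.20 and -0.07 in males and between -0.15 and -0.04 in females. The estimate of R against WT moved between -0.17 and -0.04 in males, 0.00 and 0.12 in females, and -0.05 and 0.02 over both sexes. None of the 9 genotype contrasts called Aqp3 by the edgeR quasi-likelihood test, and the differences were within the spread of the libraries. Counts per gene do not show the edited codon, so the genotype of a library was not checked.

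**Figure D1:**
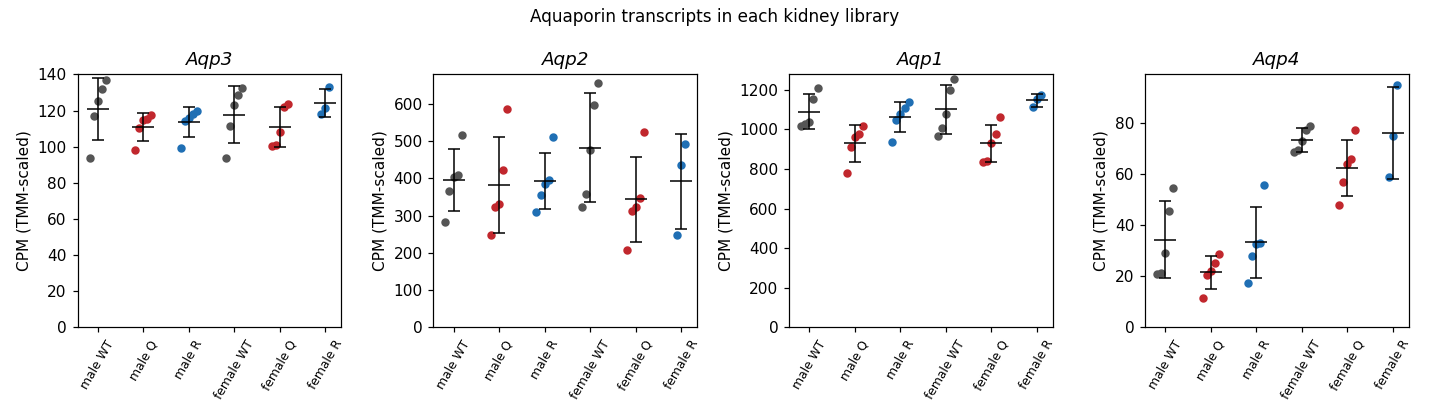
Normalised counts (CPM) of Aqp3, Aqp2, Aqp1 and Aqp4 in each library (points), with the mean and SD of each of the 6 groups. Aqp3 lies between 93.4 and 137 CPM in every library, and Aqp4 is higher in female than in male WT.

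The other aquaporins showed no change in a single gene between genotypes, adjusted over all genes. Aqp1, the water channel of the proximal tubule and thin descending limb, was 1090 ± 88.4 CPM in male WT and 929 ± 92.7 in male Q, and 1100 ± 123 in female WT and 929 ± 94.9 in female Q (SD, n = 5 each). Its log2 fold change of Q against WT over both sexes was -0.24 (SE 0.0674, edgeR adjusted p = 0.92). Aqp2, the vasopressin-regulated channel of the apical membrane, was 482 ± 146 CPM in female WT and 344 ± 115 in female Q, a log2 fold change of -0.49 (SE 0.245). Aqp4 was 34.2 ± 15 CPM in male WT and 21.5 ± 6.52 in male Q, a log2 fold change of -0.67 (SE 0.272), or -0.44 without male WT replicate 4. Aqp7, an aquaglyceroporin of the proximal tubule, had a log2 fold change of -0.29 (SE 0.11) in the same comparison. Aqp9, with 61 counts over all libraries, and Aqp12, with 0, were too low to test. Genes near Aqp3 could carry differences from the strain in which an allele was made. Of the 95 tested genes within 5 Mb, 0 changed in each genotype contrast by edgeR. With 0 genes called in these contrasts, the planned Fisher's test of changed genes could not tell. A count at an unadjusted p under 0.05 was not part of the plan. In male Q against WT it was 11 of them, 11.6% against 5.07% of other genes (one-sided Fisher's exact p = 0.00899, unadjusted for the 9 contrasts). That test takes genes measured in the same libraries as independent, so its p does not measure the spread between libraries. In the other 8 contrasts the Fisher's p of that count lay between 0.145 and 1.

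**Figure D2:**
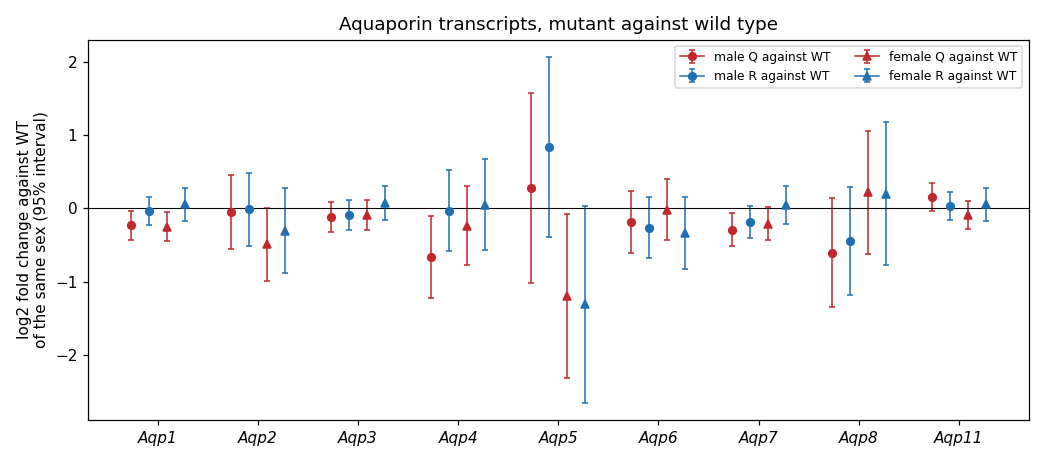
Log2 fold changes with 95% intervals of the 9 tested aquaporins for Q against WT and R against WT in each sex. No aquaporin passed an adjusted p of 0.05, and the intervals for Aqp3 include 0 in all 4 contrasts.

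Male Q kidneys were compared with male WT to ask what the acetylation mimetic alters. The list of male-biased proximal tubule genes was higher in male Q, with positive estimates for 12 of its 12 members and a median log2 fold change of 0.35. Among them were Odc1, the enzyme that starts polyamine synthesis, at 1310 ± 359 CPM in WT and 2580 ± 544 in Q (SD, n = 5 each), and Slco1a1, an organic anion transporter, at 352 ± 83.4 and 540 ± 144 CPM. Cyp2j13, a cytochrome P450, had a log2 fold change of 0.42 (SE 0.138) and Serpinf2, which encodes a plasmin inhibitor, one of 0.39 (SE 0.153), or 0.23 without male Q replicate 4. Camera called this list at an adjusted p = 0.000281, which became an adjusted p = 0.561 with an estimated correlation. Adjusted over the list alone 2 members rose, and over all genes 0 did. The immediate early genes, a set of rapidly induced transcription factors and regulators, had positive estimates for 18 of 20 members, with log2 fold changes of 2.24 (SE 0.66) for Fosb, 0.98 (SE 0.416) for Nr4a2, 0.75 (SE 0.396) for Atf3 and 0.53 (SE 0.208) for Ier3. Its camera adjusted p was 0.000706, or 0.561 with an estimated correlation, and it rose to 0.221 without male Q replicate 1. Without that library the log2 fold changes were 1.18 for Fosb, 0.59 for Nr4a2 and 0.21 for Atf3. Adjusted over the list alone 1 member rose.

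Intercalated cell genes, which serve acid and base transport in the collecting duct, were lower in male Q for 12 of 18 members. Atp6v1b1, a subunit of the proton pump, was 94.1 ± 3.87 CPM in male WT and 82.1 ± 6.46 in male Q (SD, n = 5 each). Log2 fold changes were -0.35 (SE 0.151) for the receptor kinase Kit, -0.17 (SE 0.0892) for the anion exchanger Slc26a4 and -0.30 (SE 0.193) for the metabolite receptor Oxgr1. In male Q replicate 4, a library with a larger spread than the others, Kit was 5.72 and Oxgr1 8.52 CPM. Without it their log2 fold changes were -0.20 and -0.11. Camera gave this list an adjusted p = 0.0148, or 0.561 with an estimated correlation, and 0 members passed either adjusted over the list alone or over all genes. Without male WT replicate 2 the adjusted p was 0.155, without male Q replicate 4 it was 0.0615, without both libraries that stood apart 0.0631, and with voom and quality weights 0.0505. Genes of the proximal tubule in general were lower for 14 of 18 members, with 1 falling adjusted over the list alone (camera adjusted p = 0.0171, or 0.561 with an estimated correlation). That call ended without male Q replicate 4 (0.175), male Q replicate 1 (0.0556), male WT replicate 4 (0.0526) or both libraries that stood apart (0.171), and with voom and quality weights (0.0505). Camera called these 4 lists.

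Of single genes, 0 passed the edgeR quasi-likelihood test in male Q against WT, while 897 had an unadjusted p under 0.05 and DESeq2 called 2, Kynu and Rad51c. By chance 879 genes were expected to have an unadjusted p under 0.05, in this and in each other contrast. With a replicate block edgeR called Kynu alone. The genes with the smallest p were chosen after their values were seen. Kynu, an enzyme of tryptophan breakdown, was 9.31 ± 3.08 CPM in male WT and 3.43 ± 0.943 in male Q (SD, n = 5 each), a log2 fold change of -1.44 (SE 0.25, edgeR adjusted p = 0.0651). Synpr, which encodes a synaptic vesicle protein, was 0.499 ± 0.442 and 3.91 ± 2.23 CPM, and its edgeR adjusted p was 0.0965. Rad51c, a gene of recombination repair, had a log2 fold change of 1.02 (SE 0.205) and an edgeR adjusted p of 0.152. Leaving out male WT replicate 1 brought Kynu to an edgeR adjusted p of 0.0174. Leaving out male Q replicate 5 gave 0.0177 for Kynu and 0.0111 for Synpr, so that 2 genes passed there.

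Male R kidneys were compared with male WT to ask what the deacetylation mimetic alters. Immediate early genes were higher in male R for 17 of 20 members, with a median log2 fold change of 0.52. Zfp36, which encodes an RNA-binding protein that limits cytokine messages, was 34.6 ± 9.16 CPM in WT and 53.3 ± 11.4 in R (SD, n = 5 each), and Junb, a transcription factor, was 34.3 ± 9.11 and 51.8 ± 12.8 CPM. Egr2 had a log2 fold change of 1.53 (SE 0.599), or 0.76 without male R replicate 2, and Ier2 one of 0.51 (SE 0.247), or 0.30 without male R replicate 3. Camera gave an adjusted p = 1.13e-07 for the list, or 0.487 with an estimated correlation. Intercalated cell genes were lower for 14 of 18 members, with log2 fold changes of -0.32 (SE 0.151) for Kit, -0.36 (SE 0.193) for Oxgr1, -0.18 (SE 0.0891) for Slc26a4 and -0.16 (SE 0.0918) for Atp6v1b1. That list had a camera adjusted p = 0.00372, or 0.631 with an estimated correlation, and 0.067 without male R replicate 2. Genes of the distal convoluted tubule, which reabsorbs sodium chloride and calcium, were lower for 12 of 12 members. Slc12a3, the thiazide-sensitive cotransporter, was 752 ± 87.2 CPM in WT and 653 ± 123 in R, and log2 fold changes were -0.30 (SE 0.111) for Slc8a1, -0.37 (SE 0.188) for Trpv5 and -0.23 (SE 0.148) for Calb1. The camera adjusted p was 0.0172, or 0.867 with an estimated correlation, and it was 0.0779 without male R replicate 1 and 0.168 without male WT replicate 2, where the log2 fold changes of Slc12a3 and Calb1 were -0.14 and -0.09. Adipocyte genes were higher in male R for 10 of 10 members, with a median log2 fold change of 0.83 (camera adjusted p = 0.0282, or 0.913 with an estimated correlation), a call that ended without male R replicate 2 (0.0946), 4 (0.18) or 5 (0.593) or male WT replicate 4 (0.147) or 5 (0.523). It also ended without both libraries that stood apart (0.0844) and with a replicate block (0.0702). Proximal tubule genes were lower for 15 of 18 members (camera adjusted p = 0.0282, or 0.867 with an estimated correlation), a call that ended without male WT replicate 1 (0.0935) or 4 (0.0925) or male R replicate 2 (0.0788) or 4 (0.18). Interferon response genes were higher for 12 of 14 (0.0198, or 0.913 with an estimated correlation, the call kept in 7 of 10 fits that left out a library). Renin-angiotensin genes were lower for 9 of 9 (0.0413, or 0.487 with an estimated correlation, kept in 5 of 10 such fits and lost with a replicate block at 0.0581). In each of these 7 lists 0 members passed adjusted over the list alone and 0 over all genes. Camera called 7 lists, and edgeR called 0 genes, with 375 at an unadjusted p under 0.05 and 0 by DESeq2.

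Male Q and male R kidneys were set against each other to compare the mimetics directly. Male-biased proximal tubule genes were higher in Q than in R for 12 of 12 members, with a median log2 fold change of 0.22. Odc1 was 2580 ± 544 CPM in Q and 1550 ± 674 in R, and Slco1a1 was 540 ± 144 and 343 ± 149 CPM (SD, n = 5 each). Serpinf2 and Cyp2j13 had log2 fold changes of 0.36 (SE 0.153) and 0.31 (SE 0.137), and that of Serpinf2 was 0.20 without male Q replicate 4. The list had a camera adjusted p = 0.0003, or 0.755 with an estimated correlation, and 1 member rose adjusted over the list alone. Adipocyte genes, which mark fat left on a kidney, were lower in Q for 9 of 10 members, with a median log2 fold change of -1.86. Plin1, which coats lipid droplets, was 1.17 ± 0.93 CPM in Q and 6.28 ± 6.66 in R, and Cidec was 0.989 ± 0.777 and 4.52 ± 3.77 CPM. Cidea had a log2 fold change of -2.24 (SE 1.05) and Retn, which encodes resistin, one of -1.87 (SE 0.987). The adipocyte list had a camera adjusted p = 0.00135, or 0.755 with an estimated correlation, with 0 members passing adjusted over the list alone, and it had 0.0956 without male R replicate 5, where Retn had a log2 fold change of -1.13 and Plin1 one of -1.56. Genes of 4 further lists were lower in Q, all with 0.755 with an estimated correlation. They were fatty acid oxidation (15 of 18 members, camera adjusted p = 0.00179), thin limb and inner medulla (12 of 12, 0.00273), tubule injury (9 of 14, 0.00498) and urothelium (9 of 9, 0.0126), with 1 member falling adjusted over the list alone, in tubule injury. Fatty acid oxidation had 0.196 without male Q replicate 4, 0.082 without male R replicate 4 and 0.2 without both libraries that stood apart. Thin limb had 0.0871 without male Q replicate 4, 0.0617 without male R replicate 2, 0.115 without both and 0.0681 with voom and quality weights. Tubule injury had 0.0705 without male Q replicate 3, and the urothelial call was kept in 5 of 10 fits that left out a library. Camera called 6 lists. For single genes edgeR called 0, with 721 at an unadjusted p under 0.05, and DESeq2 called 1, Gusb. Gusb, a lysosomal glucuronidase chosen after its values were seen, was 73.7 ± 12.5 CPM in Q and 47.3 ± 7.42 in R (edgeR adjusted p = 0.0978). It passed without male R replicate 4 (0.0304) and without male Q replicate 5 (0.00758), where Synpr passed too. With no filter on low counts 1 gene passed, and 2 passed with the clock score as a covariate or with voom and quality weights.

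Female Q kidneys were compared with female WT. Genes of the thin limb and inner medulla, the part of the kidney that concentrates urine, were lower in female Q for 10 of 12 members, with a median log2 fold change of -0.32. Akr1b3, the aldose reductase that makes sorbitol, was 177 ± 58.3 CPM in WT and 78.1 ± 60.2 in Q (SD, n = 5 each), although female Q replicate 2 had 185 CPM. Sptssb, a subunit for sphingolipid synthesis, was 8.25 ± 1.66 and 4.56 ± 2.3 CPM, and the log2 fold change was -0.25 (SE 0.0954) for Aqp1. Camera gave the list an adjusted p = 4.22e-06, or 0.148 with an estimated correlation. Osmolyte and tonicity genes were lower for 11 of 13 members, with log2 fold changes of -0.90 (SE 0.481) for Slc6a12, the betaine transporter, -0.37 (SE 0.195) for Slc14a2, a urea transporter, and -0.25 (SE 0.122) for Gpd1. Akr1b3 and Slc14a2 belong to both lists. The osmolyte list had a camera adjusted p = 0.00108, or 0.443 with an estimated correlation. Urothelial genes, which mark the lining of the renal pelvis, were lower for 8 of 9 members, and log2 fold changes were -0.92 (SE 0.419) for Krt5 and -0.50 (SE 0.285) for the uroplakin Upk1b, with -0.49 (SE 0.247) for Upk3b and -0.50 (SE 0.293) for Psca. That list had a camera adjusted p = 0.000575, or 0.51 with an estimated correlation. Without female Q replicate 2 the log2 fold changes were larger, at -1.79 for Akr1b3, -1.43 for Slc6a12, -1.46 for Krt5 and -0.75 for Upk1b, while that of Gpd1 was -0.11 without female Q replicate 5 and that of Upk3b -0.26 without female WT replicate 5. In these 3 lists 0 members passed adjusted over the list alone and 0 over all genes. Genes of the response to aldosterone and glucocorticoids were higher for 10 of 14 members, with 1 rising adjusted over the list alone (camera adjusted p = 0.00108, or 0.148 with an estimated correlation, and 0.0575 without female Q replicate 3). Camera called 8 lists in all, while edgeR called 0 genes, with 516 at an unadjusted p under 0.05 and 0 by DESeq2. Proximal tubule genes were lower for 15 of 18 members (camera adjusted p = 0.0291, or 0.664 with an estimated correlation), with 0.574 without female Q replicate 5, 0.582 without both libraries that stood apart and 0.81 with voom and quality weights, and the call was kept in 6 of 10 fits that left out a library. Mitochondrially encoded genes were lower for 10 of 13 (0.0011, or 0.664 with an estimated correlation), but turned higher without female Q replicate 5 (0.423) and had 0.406 without both libraries that stood apart and 0.81 with voom and quality weights. Fatty acid oxidation genes were lower for 15 of 18 (0.0151, or 0.673 with an estimated correlation), kept in 6 of 10 such fits and with 0.849 with voom and quality weights. Among the 8 was the aquaporin list, lower for 8 of 9 members (camera adjusted p = 0.00572, or 0.148 with an estimated correlation). Female Q replicate 2 had the highest mean of its group in the aquaporin, thin limb, osmolyte and urothelial lists. Falls in these lists need not be separate results.

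Female R kidneys, with 3 libraries, were compared with the 5 of female WT. Endothelial genes were lower in female R for 11 of 11 members, with a median log2 fold change of -0.11. Plvap, a component of the diaphragms of fenestrated capillaries, was 240 ± 21.5 CPM in WT (SD, n = 5) and 195 ± 17.3 in R (n = 3), and Tek, the angiopoietin receptor, was 49.8 ± 4.23 and 40.5 ± 5.31 CPM. Emcn and Pecam1, both surface glycoproteins of endothelium, had log2 fold changes of -0.29 (SE 0.134) and -0.27 (SE 0.129). This list had a camera adjusted p = 0.00013, or 0.229 with an estimated correlation. Urothelial genes were lower for 9 of 9 members, with log2 fold changes of -0.78 (SE 0.27) for Krt15, -0.82 (SE 0.349) for Psca, -0.57 (SE 0.335) for Upk1b and -0.44 (SE 0.289) for Upk3b. Camera gave it the same adjusted p = 0.00013, or 0.404 with an estimated correlation. Adipocyte genes were lower for 10 of 10 members, with log2 fold changes of -1.16 (SE 1.1) for Cfd, -0.99 (SE 1) for Cidec and -0.62 (SE 0.448) for Car3. The adipocyte list had a camera adjusted p = 0.000367, or 0.737 with an estimated correlation, and it had 0.818 without female R replicate 2 and 0.0526 without female WT replicate 5. Without female R replicate 2 the log2 fold changes were -0.59 for Cfd, -0.43 for Cidec, -0.32 for Car3 and -0.26 for Upk1b, and without female R replicate 1 they were -2.86, -3.06, -1.36 and -0.93. Upk3b had -0.22 without female WT replicate 5. Lists for other cell types and pathways were called beside the endothelial list. Stroma and pericyte genes were lower for 10 of 12 members (camera adjusted p = 0.0023, or 0.404 with an estimated correlation, and 0.554 without female R replicate 1). Thin limb and inner medulla genes were lower for 9 of 12 (0.000939, or 0.404 with an estimated correlation, and 0.126 without female R replicate 2). Proximal tubule genes were higher for 15 of 18 (0.0248, or 0.737 with an estimated correlation), a call that ended without female R replicate 2 (0.163) or 3 (0.331) or female WT replicate 2 (0.178), with a replicate block (0.146) and with voom and quality weights (0.0509). Interferon response genes were lower for 13 of 14 (0.0248, or 0.783 with an estimated correlation), but turned higher without female WT replicate 2 (0.653). Immediate early genes were lower for 18 of 20 (0.00357, or 0.737 with an estimated correlation, and 0.593 without female R replicate 1). Each of these 2 calls was kept in 5 of 8 fits that left out a library, and that on interferon ended with voom and quality weights (0.0501). In all 8 lists 0 members passed adjusted over the list alone and 0 over all genes. Camera called 8 lists, and edgeR called 0 genes, with 338 at an unadjusted p under 0.05 and 0 by DESeq2.

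Between female Q and female R, proximal tubule genes were lower in Q for 17 of 18 members, with a median log2 fold change of -0.17. Slc3a1 and Slc7a9, the subunits of the cystine transporter, were 497 ± 54.7 and 154 ± 9.78 CPM in Q (SD, n = 5) and 606 ± 74.7 and 183 ± 25 CPM in R (n = 3). Slc6a19, a transporter of neutral amino acids, had a log2 fold change of -0.36 (SE 0.175) and Aqp1 one of -0.30 (SE 0.109). The list had a camera adjusted p = 0.000155, or 0.419 with an estimated correlation, and without female R replicate 2 log2 fold changes were -0.18 for Slc3a1, -0.23 for Slc6a19 and -0.12 for Slc7a9. Genes of oxidative phosphorylation encoded by the mitochondrial genome were lower in Q for 12 of 13 members, with log2 fold changes of -0.53 (SE 0.331) for mt-Nd5, -0.37 (SE 0.291) for mt-Nd2, -0.33 (SE 0.235) for mt-Cytb and -0.28 (SE 0.214) for mt-Co1. Female Q replicate 5 stood apart in these genes, with 13300 CPM of mt-Co1 against a group mean of 33200 ± 11200 CPM (SD, n = 5). The mitochondrial list had a camera adjusted p = 0.000242, or 0.663 with an estimated correlation, and it had 0.364 without female Q replicate 5, where log2 fold changes were -0.27 for mt-Nd5, -0.10 for mt-Nd2, -0.09 for mt-Cytb and -0.08 for mt-Co1, and 0.237 without both libraries that stood apart. Markers of other cell types were higher in Q. Stroma and pericyte genes were so for 11 of 12 members (camera adjusted p = 0.000285, or 0.419 with an estimated correlation, and 0.2 without female R replicate 1). Endothelial genes were so for 9 of 11 (0.016, or 0.549 with an estimated correlation), a call that ended without female R replicate 1 (0.187) or female Q replicate 2 (0.0606) or 4 (0.0733). Adipocyte genes were so for 9 of 10 (0.0434, or 0.75 with an estimated correlation), kept in 3 of the 8 fits that left out a library, turned to lower without female R replicate 2 (0.652) and ended with voom and quality weights (0.211). Fatty acid oxidation genes were lower for 15 of 18 (0.0439, or 0.687 with an estimated correlation), kept in 4 of 8 such fits and lost with a replicate block (0.726) or voom and quality weights (0.251). In these 6 lists 0 members passed adjusted over the list alone and 0 over all genes. Camera called 6 lists, and edgeR called 0 genes, with 532 at an unadjusted p under 0.05 and 0 by DESeq2.

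Over both sexes, thin limb and inner medulla genes were lower in Q than in WT for 12 of 12 members, with log2 fold changes of -0.56 (SE 0.209) for Calca, -0.55 (SE 0.289) for Sptssb, or -0.27 without male WT replicate 2, and -0.21 (SE 0.113) for Slc4a11 (camera adjusted p = 5.13e-05, or 0.206 with an estimated correlation). Aquaporins were lower for 8 of 9 members, with log2 fold changes of -0.24 (SE 0.0674) for Aqp1, -0.25 (SE 0.0775) for Aqp7, -0.45 (SE 0.189) for Aqp4 and -0.27 (SE 0.173) for Aqp2. The aquaporin list had a camera adjusted p = 0.0017, or 0.123 with an estimated correlation, and an adjusted p of 0.0546 by fry. Proximal tubule genes were lower for 16 of 18 members, with log2 fold changes of -0.27 (SE 0.0827) for Slc7a9, -0.27 (SE 0.108) for Slc6a19 and -0.19 (SE 0.0836) for Slc3a1 (camera adjusted p = 0.0017, or 0.38 with an estimated correlation). Slc3a1 had -0.12 without male Q replicate 4. Without both libraries that stood apart this call ended, at an adjusted p = 0.157, and it ended with voom and quality weights, at 0.102. Male-biased proximal tubule genes were higher for 10 of 12 members, with a log2 fold change of 0.59 (SE 0.151) for Odc1 (camera adjusted p = 0.0017, or 0.38 with an estimated correlation). In females alone 7 of 12 were positive, with a median of 0.06 and a camera adjusted p = 0.629, against 12 of 12 and 0.35 in males, and the interaction of sex with Q had a camera adjusted p = 0.0322, or 0.88 with an estimated correlation. Genes of the response to aldosterone and glucocorticoids were higher for 10 of 14 members (camera adjusted p = 0.00487, or 0.319 with an estimated correlation). Also lower were urothelial genes for 9 of 9 members (0.00202, or 0.563 with an estimated correlation, and 0.0616 without male WT replicate 2). Without both libraries that stood apart, 3 other falls ended: osmolyte and tonicity genes (12 of 13, 0.0214, then 0.26), mitochondrially encoded genes (11 of 13, 0.0174, then 0.725) and fatty acid oxidation (13 of 18, 0.0169, then 0.191). Each of the 3 had 0.626 with an estimated correlation, and with voom and quality weights they had 0.107, 0.239 and 0.777. Of 20 fits that left out a library, these 3 calls were kept in 14, 16 and 14. The osmolyte and fatty acid oxidation calls also ended without male WT replicate 2 (0.256 and 0.119), which is not among the libraries that stood apart. Adjusted over the list alone, 2 aquaporins fell, 2 proximal tubule genes fell, 1 thin limb gene fell, 1 male-biased gene rose and 1 gene of the hormone response rose, against 0 over all genes. Aqp1 belongs to the aquaporin, proximal tubule and thin limb lists, so these falls need not be separate genes. The aquaporin, thin limb, osmolyte and urothelial lists also moved together in some libraries. Male WT replicate 2, female Q replicate 2 and female R replicate 1 had the highest mean of their group in each of these lists. No library did so in the other groups. Whether these falls follow the share of medulla and pelvis in each sample was not tested, so they cannot be told apart from it. Camera called 9 lists. By edgeR 0 genes changed, with 829 at an unadjusted p under 0.05, and DESeq2 called 1, Kynu, whose log2 fold change was -0.82 (SE 0.163, edgeR adjusted p = 0.491). Kynu was also the 1 gene called by edgeR with a replicate block or with only the libraries of the contrast.

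For R against WT over both sexes, endothelial genes were lower for 11 of 11 members, with a median log2 fold change of -0.09. Log2 fold changes were -0.18 (SE 0.0852) for Pecam1, -0.16 (SE 0.0767) for Plvap, -0.12 (SE 0.072) for Tek and -0.10 (SE 0.0715) for Tie1, a receptor kinase of endothelium, and without female R replicate 1 those of Tek and Tie1 were -0.07 and -0.06. Camera gave this list an adjusted p = 0.00152, or 0.228 with an estimated correlation, and 0.0683 without male R replicate 4. Skeletal muscle genes were the other list called, at a camera adjusted p = 0.0465, or 0.228 with an estimated correlation, with a log2 fold change of 0.40 (SE 0.189) for the creatine kinase Ckm, and this call was kept in 7 of the 18 fits that left out a library. It ended without both libraries that stood apart (0.0771), with a replicate block (0.0726), with voom and quality weights (0.102) and with DESeq2's size factors (0.0501). By edgeR 0 genes changed, with 235 at an unadjusted p under 0.05 and 0 by DESeq2. For Q against R over both sexes, genes of fatty acid oxidation were lower in Q for 16 of 18 members. Log2 fold changes were -0.43 (SE 0.148) for Cyp4a10, which hydroxylates fatty acids, -0.27 (SE 0.115) for Acot1 and -0.14 (SE 0.0772) for Hadha. This list had a camera adjusted p = 0.000447, or 0.563 with an estimated correlation. Mitochondrially encoded genes were lower for 12 of 13 members, with log2 fold changes of -0.22 (SE 0.142) for mt-Co1 and -0.20 (SE 0.156) for mt-Cytb, both lowest in female Q replicate 5 among female Q libraries. That list had a camera adjusted p = 0.00161, or 0.563 with an estimated correlation, and 0.0557 without female Q replicate 5, where mt-Co1 had a log2 fold change of -0.12 and mt-Cytb one of -0.08. In these lists 0 members passed adjusted over the list alone and 0 over all genes. Beside these, proximal tubule genes were lower for 15 of 18 members (camera adjusted p = 0.00196, called in all 18 fits that left out a library), with 0.174 without both libraries that stood apart and 0.192 with voom and quality weights. Stroma and pericyte genes were higher for 10 of 12 (0.0238) and endothelial genes for 9 of 11 (0.0242), with 0.353 and 0.231 without female R replicate 1. Thin limb and inner medulla genes were lower for 11 of 12 (0.0237), with 0.33 without female R replicate 1 and 0.0865 without both libraries that stood apart. Lower as well were aquaporins for 8 of 9 (0.0287, kept in 8 of 18 fits that left out a library) and osmolyte and tonicity genes for 11 of 13 (0.0444, kept in 6 of 18, and 0.394 without both). Male-biased proximal tubule genes were higher for 8 of 12 (0.0318, kept in 9 of 18, 0.23 without both and 0.0521 with voom and quality weights). All 9 lists had 0.563 with an estimated correlation, and adjusted over the list alone 2 proximal tubule, 1 thin limb and 1 aquaporin gene fell and 2 male-biased genes rose. The falls need not be separate genes, as Aqp1 belongs to the proximal tubule, thin limb and aquaporin lists. The thin limb, aquaporin and osmolyte lists also moved together in some libraries. Camera called 9 lists for Q against R, and edgeR called 0 genes, with 691 at an unadjusted p under 0.05 and 0 by DESeq2.

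Interaction terms asked whether a genotype's difference from WT was unlike in females and males. For R, immediate early genes had a lower difference in females for 20 of 20 members, with a median interaction of -0.63 on the log2 scale. Junb was 47.8 ± 17.2 CPM in female WT (SD, n = 5) and 38 ± 15.5 in female R (n = 3), while it was 34.3 ± 9.11 and 51.8 ± 12.8 CPM in male WT and male R (n = 5 each). Interaction estimates were -2.18 (SE 0.951) for Egr2, -0.81 (SE 0.377) for Ier2 and -1.79 (SE 1.05) for Fosb. The list had a camera adjusted p = 1.13e-07, or 0.397 with an estimated correlation. Adipocyte genes had negative interactions for 10 of 10 members, with -2.19 (SE 1.36) for Plin1, -1.90 (SE 1.32) for Cidec, -1.19 (SE 0.585) for Car3 and -0.77 (SE 0.518) for Fabp4. That list had a camera adjusted p = 0.000127, or 0.442 with an estimated correlation, and 0.0774 without female R replicate 2. Single libraries moved these estimates, to -4.17 for Plin1, -3.98 for Cidec, -1.93 for Car3 and -0.54 for Ier2 without female R replicate 1, -1.41 for Egr2 without male R replicate 2, -1.07 and -3.17 for Fosb without female WT replicate 4 and without female R replicate 3, and -0.39 for Fabp4 without male R replicate 5. Plin1 had -1.35 without male R replicate 5 and -1.44 without female WT replicate 5. For Q, immediate early genes had negative interactions for 18 of 20 members, with -2.18 (SE 0.921) for Fosb, -1.42 (SE 0.567) for Nr4a2, -1.18 (SE 0.861) for Egr2 and -0.91 (SE 0.491) for Jun. Its camera adjusted p was 0.00331, or 0.88 with an estimated correlation, and it was 0.254 without male Q replicate 1, where Fosb had -1.12 and Jun -0.51, and 0.0582 without male WT replicate 3. In these lists 0 members passed adjusted over the list alone and 0 over all genes. Camera called 10 lists in the interaction with R and 2 in that with Q. Single genes gave 0 calls by edgeR in both interactions, with 495 for R and 547 for Q at an unadjusted p under 0.05, and 0 by DESeq2.

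Female and male WT kidneys were compared as the background of sex against which the genotypes were read. In female WT 2906 genes changed by the edgeR quasi-likelihood test, with 1461 higher and 1445 lower, and 747 of them by at least 2-fold. The lower ones included transporters and enzymes of the male proximal tubule. Slc7a13, an aspartate and glutamate transporter, fell from 1140 ± 64.8 CPM in male WT (SD, n = 5) to a mean of 5.51 in female WT, a log2 fold change of -7.69 (SE 0.203, edgeR adjusted p = 3.9e-23), and Slco1a1 fell from 352 ± 83.4 to 1.21 ± 0.336 CPM. Cyp2j13, the fatty acid activating enzyme Acsm3, the protease inhibitor Pzp and the plasma glycoprotein gene Apoh fell as well, with log2 fold changes of -7.53 (SE 0.197), -6.97 (SE 0.438), -7.77 (SE 0.289) and -7.32 (SE 0.485). Mpped1 had 836 counts in male and 2 in female WT, a ratio of 439 (95% interval 121 to 3630). Neurog2, a neuronal transcription factor gene, had 0 counts in female WT, at least 141-fold lower for pooled counts against the floor of 3 counts over the group. Male WT libraries ran from 0.0484 to 10.8 CPM (4.81 ± 4.5, SD, n = 5), so that fold does not hold for each library. Neurog2 did not pass in a fit of only the WT libraries (edgeR adjusted p = 0.0853). Higher in females were Ugt1a2, a glucuronosyltransferase, at 2.18 ± 0.863 CPM in male and 515 ± 81.7 in female WT (edgeR adjusted p = 5.59e-18), and the conjugate exporter Abcc3, at 2.8 ± 0.975 and 90 ± 45.2 CPM. Slc17a2, the protease gene Tmprss6, the cation pump gene Atp13a4, Ugt1a1 and the growth factor gene Igf2 rose too, with log2 fold changes of 5.51 (SE 0.286), 6.37 (SE 0.49), 4.72 (SE 0.525), 4.76 (SE 0.554) and 4.94 (SE 0.859). Myh1, a myosin heavy chain, had 3 counts in male and 341 in female WT, a ratio of 108 (95% interval 36.7 to 527). Members of the Ugt1a and Cyp families share sequence, so counts of a single member are less certain.

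By list, 12 of the 12 male-biased proximal tubule genes fell in female WT, over all genes and adjusted over the list alone, with a median log2 fold change of -4.49. Cyp4b1 fell from 3480 ± 608 to 135 ± 39.2 CPM and Cyp2e1 from 1260 ± 177 to 63.8 ± 5.51 CPM (SD, n = 5 each). Camera gave this list an adjusted p = 1.97e-39, and it held at an adjusted p = 4.09e-06 with an estimated correlation. The female-biased proximal tubule list was not called (camera adjusted p = 0.382), since 5 of its 10 members rose, among them Abcc3 and the transporter Slc7a12 with a log2 fold change of 4.41 (SE 0.566), and 4 fell, among them Acsm2 with -1.94 (SE 0.107) and Cyp2a4 with -1.35 (SE 0.159). Interferon response genes rose in 9 of 14 cases, or 12 adjusted over the list alone, with log2 fold changes of 0.70 (SE 0.133) for Ddx58, 0.96 (SE 0.191) for Ifit3, or 0.62 without female WT replicate 2, and 0.80 (SE 0.179) for Oasl2. That list had a camera adjusted p = 0.000137, or 0.275 with an estimated correlation. In female WT replicate 2, the library without Xist, Oasl2 stood at 18.5 CPM against a mean of 11.9 ± 3.76, and without it the camera adjusted p was 0.0015.

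Several lists of the distal nephron and collecting duct were higher in female WT. Of 15 principal cell genes 8 rose, or 11 adjusted over the list alone. Aqp4 rose from 34.2 ± 15 to 73.3 ± 4.65 CPM (SD, n = 5 each, edgeR adjusted p = 0.00458), the transcription factor Gata3 had a log2 fold change of 0.71 (SE 0.186) and the potassium channel Kcnj1 one of 0.45 (SE 0.1). Camera gave this list an adjusted p = 0.00043, or 0.0677 with an estimated correlation. Of 13 thick ascending limb genes 6 rose, or 11 adjusted over the list alone, with log2 fold changes of 1.17 (SE 0.233) for Enox1 and 0.36 (SE 0.0974) for Bsnd (camera adjusted p = 0.000649, or 0.0677 with an estimated correlation). Of 18 intercalated cell genes 5 rose, or 14 adjusted over the list alone, with log2 fold changes of 0.42 (SE 0.0917) for Atp6v1b1 and 0.44 (SE 0.11) for Atp6v0d2 (camera adjusted p = 0.00043, or 0.21 with an estimated correlation). Of 12 thin limb and inner medulla genes 6 rose, or 8 adjusted over the list alone, with log2 fold changes of 1.07 (SE 0.161) for Slc4a11 and 0.67 (SE 0.167) for Cldn4 (camera adjusted p = 0.000649, or 0.21 with an estimated correlation). Podocyte genes rose in 7 of 9 cases, or 8 adjusted over the list alone (camera adjusted p = 0.00146, or 0.275 with an estimated correlation). The aquaporin list was not called (camera adjusted p = 0.649), as Aqp4 rose and Aqp8 fell, with a log2 fold change of -1.61. Aqp5 and Aqp6 had edgeR adjusted p of 0.0516 and 0.0921, and of 0.0152 and 0.0106 without male WT replicate 2. For Aqp6 that library was the highest of male WT (93.6 CPM, the nearest at 59.5). Female WT replicate 2 was likewise the highest of its group (146 CPM, the nearest at 75.1), so leaving out the male one alone widens the difference of Aqp6. Stroma and pericyte genes rose in 6 of 12 cases (10 adjusted over the list alone, camera adjusted p = 0.00156, or 0.21 with an estimated correlation) and distal convoluted tubule genes in 4 of 12 (8 adjusted over the list alone, camera adjusted p = 0.00377, or 0.282). Genes of vasopressin and urea handling rose in 5 of 18 cases (9 adjusted over the list alone, camera adjusted p = 0.00539, or 0.275 with an estimated correlation) and endothelial genes in 4 of 11 (4 adjusted over the list alone, camera adjusted p = 0.021, or 0.279). Immediate early genes rose in 2 of 20 cases (1 adjusted over the list alone, camera adjusted p = 0.0201, or 0.553), a call that ended without female WT replicate 4 (0.0564) or male WT replicate 3 (0.0684). Camera called 13 of the 31 lists, and of these the male-biased proximal tubule list and the Y-linked list held with an estimated correlation. In the 9 genotype contrasts and the 2 interactions 0 lists held with it. DESeq2 called 3220 genes between the sexes, and voom with quality weights called 4623, of which 2863 were among the 2906.

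**Figure D3:**
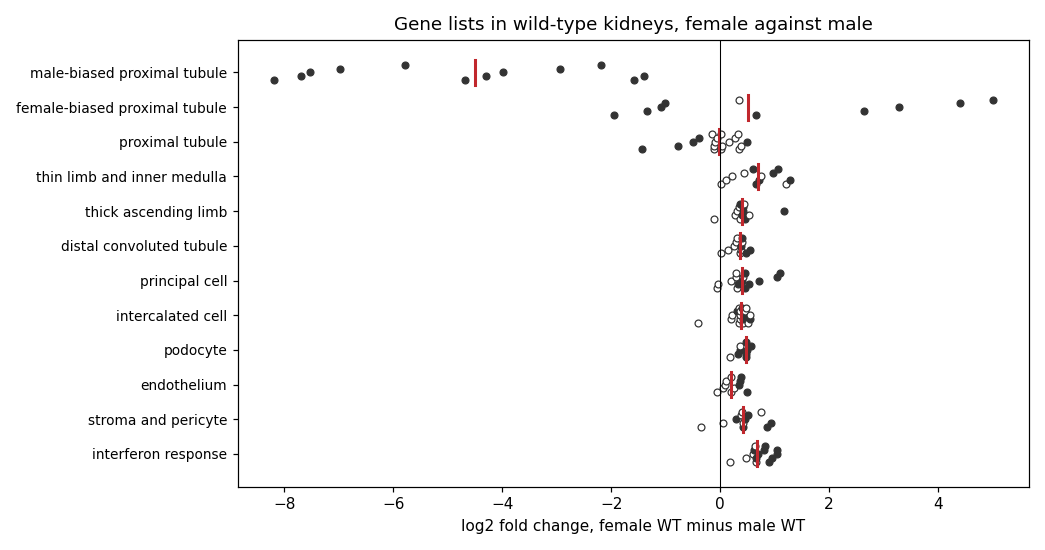
Log2 fold changes of female against male WT for the members of 12 gene lists (points), filled where the adjusted p was under 0.05, with each list's median as a red bar. The male-biased proximal tubule list has the lowest median of the 12, -4.49, and the medians of the principal and intercalated cell lists lie above 0.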

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

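The tests of the 3 patterns weighed here were chosen only after the results were seen, whereas the splits of the samples, the search for libraries that stand apart and the interaction terms were planned. For chance in the sex score, the demand that it also pass without each library was added after a first reading, and so was Fisher's test of the Q allele. That test replaced a count, 7 of the other 8 Q libraries at or above the lowest weight of WT and R, which could not tell the explanations apart. Libraries that stand apart from their group were sought with Dixon's test among the named genes in groups of 5, where chance flags about 1 in 20 groups. It marked 35 of 332 groups, 10.5%, with 6 of the marks in male Q replicate 4 and 4 each in female Q replicate 5, female WT replicate 2 and male WT replicate 2.

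Male Q replicate 4 was the lowest of its group in Kit (5.72 CPM, the nearest library at 10.9), Oxgr1 (8.52), Slc3a1 (274), mt-Co1 (19500) and Cyp4b1 (2920), and the highest in Serpinf2 (674). Female Q replicate 5 was the lowest in mt-Co1 (13300 CPM, the nearest at 36400), mt-Cytb (5210) and mt-Nd2 (1260) and the highest in Hao2, a peroxisomal oxidase (1240). Female WT replicate 2 was the highest in Aqp6 (146 CPM), Cyp4a12a (4.17) and Oasl2 (18.5) and the lowest in Enox1 (2.15). Male WT replicate 2 was the highest in Aqp6 (93.6 CPM) and in the fat genes Cidec (6.9), Fabp4 (82) and Plin1 (7.2). In the female Q group, replicate 2 had 185 CPM of Akr1b3, the nearest library 56.9. Stress-induced genes stood apart in male R, with 2.69 CPM of Egr2 in replicate 2, 30.6 of Ier2 in replicate 3 and 29.1 of Junb, the lowest, in replicate 1. They did so in male WT replicate 1, with 50.9 CPM of Zfp36 and 99.8 of Jun, and in female WT replicate 4, with 2.34 CPM of Fosb. Male R replicate 4 was the lowest of its group in Aqp3 (99.1 CPM, the nearest at 114) and the highest in Acot1 (161). The alcohol dehydrogenase Adh1 was highest in male WT replicate 4 (670 CPM), Cidea in male Q replicate 3 (2.76), Serpinf2 in female WT replicate 3 (119), the muscle actin Acta1 in female WT replicate 1 (31), Myh1 in male R replicate 2 (0.236), Atp13a4 in male WT replicate 3 (0.387) and Igf2 in female WT replicate 4 (3.8). Kcnj1 was lowest in female WT replicate 1 (292 CPM).

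The difference of R from WT was unlike in females and males for 10 lists by the camera test of the interaction. Higher in females were intercalated cell genes (adjusted p = 0.0252), distal convoluted tubule genes (0.0151) and proximal tubule genes (0.00226). Lower in females were genes of the thin limb and inner medulla (0.00436), endothelium (0.0191), stroma and pericytes (0.0127), the interferon response (0.0017), immediate early genes (1.13e-07), adipocytes (0.000127) and urothelium (0.000591). For Q the lower ones were male-biased proximal tubule genes (0.0322) and immediate early genes (0.00331). With an estimated correlation the smallest adjusted p was 0.397 for R and 0.88 for Q, so none held. Adjusted over the list alone 5 thin limb genes fell in the interaction with R. The calls on proximal tubule, thin limb and urothelium, and that on immediate early genes for R, passed in all 18 fits that left out a library. Of the others, the highest adjusted p was 0.233 for intercalated cells without female WT replicate 1 (0.118 with a replicate block), 0.122 for the distal convoluted tubule without male WT replicate 2, 0.138 for endothelium and 0.34 for stroma without female R replicate 1, 0.285 for interferon without female WT replicate 2 and 0.0774 for adipocytes without female R replicate 2. For Q it was 0.154 for the male-biased list without male Q replicate 3, which passed in 10 of 20 such fits, and 0.254 for immediate early genes without male Q replicate 1.

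Genes that differ between the sexes were shifted towards the male side in male Q kidneys: a score, the mean log2 level of male-biased less that of female-biased autosomal genes chosen in libraries outside the comparison (382 and 387 genes), was 3.15 ± 0.12 in male Q and 2.79 ± 0.192 in male WT (SD, n = 5 each), and all 5 male Q libraries lay above all 5 of male WT (exact permutation p = 0.00794, two-sided, the smallest that 5 against 5 can give). Over the 6 comparisons within a sex the adjusted p was 0.0476, and it stayed there when any one male WT library was left out. When any one male Q library was left out it was 0.0714 to 0.143, with differences of 0.329 to 0.393. As the call ended there, and as the score was made after the shift was seen in these libraries, chance is not excluded. Without male Q replicate 4 the difference was 0.334, from 0.363, with an exact permutation p of 0.0317 that passes unadjusted and an adjusted p of 0.143 that does not, so the part of that library is weakened rather than settled. A larger share of proximal tubule would raise its general markers, but their median log2 fold change was -0.126, with 14 of 18 lower. Without male Q replicate 4 that list stayed on the lower side, but its camera adjusted p was 0.175. The list does not part the segments of the tubule, so a larger share of a single segment was not tested. A difference between the groups in age, litter or hormonal state, which the labels do not give, stays open as well. An effect of the Q allele on androgen-dependent genes is thus a hypothesis found and tested on the same data. It could also rest on such differences.

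Female WT replicate 2 lacked Xist, with 0.515 CPM against 214 to 435 in the other 12 female libraries. A male library under a female label is argued against by its Y-linked genes, which summed to 0.468 CPM where the lowest male had 121. Loss of Xist with both X chromosomes active would raise X-linked genes, but their median relative to autosomal genes was -0.0341 on the log2 scale, within the -0.0516 to 0.0834 of the other females. A single X chromosome may be present, as 6 genes that escape silencing had a median of -0.519, below the -0.205 to 0.262 of the other females. The design gives no group that differs in this way, and the chromosomes themselves were not examined.

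Male Q replicate 4 and female Q replicate 5 stood apart from the other 26 libraries in spread, with quality weights of 0.0991 and 0.232 against 0.535 to 1.86. In male Q replicate 4 the log2 deviation from the mean of the other male libraries, of all genotypes, fell with transcript length. Its slope was -0.254 against -0.115 to 0.0905 in the others, so a length bias may be part of its difference. For female Q replicate 5 the slope was -0.0806, within the others' range, which argues against length bias there, and its mitochondrially encoded genes held 3.94% of counts against 9.56 to 12.1% in the others. Both are Q libraries, 2 of 10 against 0 of 18 of WT and R (one-sided Fisher's exact p = 0.119). With 2 libraries apart this is the smallest p the test can give, so it cannot tell the Q allele as the source from chance. The handling of these 2 samples stays open too, as the labels give no batch or quality value.

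Other splits of the same samples were run for each count. Between female and male WT, chance can be excluded for the 2906 genes, as 1 of 100 splits, the real one, gave as many, and the highest other gave 203. For the number of lists called, 13, it cannot be excluded, with 19 of 100 splits and a highest other of 16. That count says nothing about a single list, and the male-biased proximal tubule and Y-linked lists held with an estimated correlation (adjusted p = 4.09e-06 and 1.2e-06). For the genotype contrasts and interactions the real count was 0 genes, which all 100 splits (all 56 in the 2 female contrasts with R) reach, so these splits say nothing about chance. The highest other split called 21 genes in male Q against WT, 6 in male R against WT, 2 in female Q against WT, 0 in female R against WT, 1 in female Q against R, 3 and 6 in Q and R against WT over both sexes, and 0 in both interactions. It called 1333 genes in male Q against R and 395 in Q against R over both sexes, although such splits do not follow the genotype labels, and the cause was not tested. Chance cannot be excluded for the lists called either. As many as the real 4, 7 and 6 lists came in 36, 23 and 11 of 100 splits for male Q against WT, R against WT and Q against R, with highest others of 12, 13 and 11. In females the real 8, 8 and 6 came in 54 of 100, 25 of 56 and 28 of 56 splits, with highest others of 15, 13 and 13. Over both sexes the real 9, 2 and 9 came in 16, 98 and 9 of 100 splits, with highest others of 14, 14 and 13. For the interactions of sex with Q and with R the real 2 and 10 came in 93 and 14 of 100 splits, with highest others of 12 and 13.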

How the results depend on the processing

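Limma with voom and quality weights, and leaving out together the 2 libraries that stood apart, were chosen only after the data were seen; all other tests named here were planned. The count of 0 genes held in every setting for male R against WT, female Q against WT, female R against WT, female Q against R, R against WT and Q against R over both sexes, and both interactions, by edgeR, DESeq2 and voom. In these contrasts 235 to 547 or, for Q against R over both sexes, 691 genes had an unadjusted edgeR p under 0.05, fewer than the 879 expected by chance. In male Q against WT the count became 1 with a replicate block and 2 by DESeq2, and 0 to 2 with each library left out. In male Q against R it became 1 with no filter on low counts and 1 by DESeq2, 2 with the clock score as a covariate and 2 with voom and quality weights, and 0 to 2 with each library left out. In Q against WT over both sexes it became 1 with a replicate block, 1 with only the libraries of the contrast and 1 by DESeq2. The cause of these was not tested.

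Between female and male WT 2260 to 4331 genes changed in the other settings and 4623 with voom and quality weights, and 46.2 to 50.7% of them were higher in females. The cause of the larger count was not tested, though without male Q replicate 4 alone edgeR called 3873, of which 2903 were among the 2906. Each library of the comparison left out in turn gave 2356 to 2821. Over the 12 contrasts 84 list calls were made by camera, 2 with an estimated correlation and 15 by fry, all of the last 2 counts in female against male WT, and the cause was not tested. The other settings gave 80 to 95 calls and leaving out each library 68 to 96.

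The residuals gave no clear pairing of libraries by replicate number, but no chance rate was computed, so a pairing is not excluded. Correlations of residuals between libraries of one number ran from -0.234 to 0.188 in males and from -0.166 to 0.104 in females, and 2 of 15 male and 6 of 13 female libraries correlated best with one of their own number. Of 5425 comparisons for 257 results on named genes, 5379 kept their side of the threshold, 20 lost and 26 gained a call. A reversal, a change of sign in a gene called in either fit or over 2 SE from 0, came in 0. Uncalled genes within 2 SE of 0 could change sign and still count among the 5379. Those that lost it were Calca, Irf7, Neurog2, Rhcg, Slc26a4, Sptssb and Synpr between the sexes. Aqp3's neighbours had 0 changed genes in every setting, with 48 tested within 2 Mb and 151 within 10 Mb. The median SE of a log2 fold change was 0.164 to 0.189 within a sex. Simulated changes of 1.5-fold, with 200 genes of at least 1 CPM changed at once, were recovered in 29.9 to 56.7% of genes. Changes of that size in single genes can thus be missed with groups of this size. A lone or lower-level gene may be missed more often, which was not simulated.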

Other observations

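The test of the sex score in the comparisons other than male Q against WT was chosen only after the result there was seen; the other values are descriptive. Fat and brown fat genes varied widely between single kidneys of every group. Ucp1, the uncoupling protein of brown fat, ran from 0 to 18.8 CPM, Cidea from 0.0559 to 18.5, Plin1 from 0.184 to 17.4, Adipoq from 0.112 to 13.1 and the adipokine gene Cfd from 0.123 to 72.9 CPM. Female WT replicate 5 was highest in Ucp1, Cidea and Cfd, and male R replicate 5 in Plin1 and Adipoq. Star, which serves steroid synthesis in the adrenal gland, stayed between 1.87 and 3.82 CPM.

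Clock and stress-induced genes also ranged widely within the window of 2 to 5 h. Dbp, a clock output gene, ran from 7.32 to 84.1 CPM, Arntl from 5.48 to 28.5, Nr1d1 from 21.2 to 82.4 and Per1 from 8.3 to 34.1 CPM. Fos ran from 0.928 to 16.6 and Egr1 from 6.78 to 54.1 CPM, both highest in male Q replicate 1, the library whose omission ended the call on immediate early genes in male Q.

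Several single genes that differ between the sexes in WT stood out in male Q, and they were chosen after their values were seen. Hao2, higher in females, was 266 ± 93.6 CPM in male WT and 140 ± 31.6 in male Q (SD, n = 5 each), and Kynu, higher in females too, was 59.8 ± 3.94 CPM in female WT. Gusb was 52.7 ± 8.26 CPM in male WT and 73.7 ± 12.5 in male Q. The sex score differed by 0.334 between male Q and male R (exact permutation p = 0.0159, two-sided, adjusted p = 0.0477 over 6 comparisons) and by 0.0375 between male R and male WT (exact permutation p = 0.706, two-sided). In females the exact permutation p was 0.317 for Q against WT, 0.268 for R against WT and 0.179 for Q against R, and the difference between the sexes in this shift was not tested by the score.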
